A study of Mus musculus with 6 samples.

How the data were processed

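Gene expression was measured in fully grown mouse oocytes at the germinal vesicle (GV) stage, arrested in meiotic prophase with an intact nucleus. They came from XX females and from XY females of B6.Y(TIR), a strain in which a Y chromosome of Tirano origin on the C57BL/6 background leaves XY animals able to develop ovaries. Per the labels' protocols, females aged 25 to 29 days received 5 IU of equine chorionic gonadotropin, and oocytes were taken 45 to 47 hours later and stripped of cumulus cells by pipetting. RNA of 10 oocytes per sample, from 3 XX and 3 XY females, went through a 2-cycle labelling with oligo(dT) primers and onto an Affymetrix 3' expression array. The protocols also mention XO females and growing oocytes, which were not analysed here.

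The deposited table holds 1 intensity per probe set and array on a linear scale, and MAS5 is the only tool that the submitters' processing notes name. Its version, target value and detection calls are not given in the sources used here. The deposited intensities did not share a common level: the mean after trimming 2% at each end ran from 194 to 332 between arrays, and the median from 24.5 to 31.4. The planned design had assumed values already scaled by MAS5. Because they were not, quantile normalization between the 6 arrays became the main setting before any test was run, and the deposited values became an alternative. Quantile normalization gives every array the same distribution, so a change in the total amount of mRNA cannot be seen.

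The table held 64 control probe sets and 45037 others. The platform annotation paired 34945 of these with 1 gene symbol, 932 with several and 9160 with none listed. Of the first, 34741 matched the mouse gene table of assembly GRCm38.p6 by gene ID, which gave current symbols and the chromosome. Probe sets with several symbols or none were not named. All 6 value columns were used.

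Analyses were run in R 4.3.3 with limma 3.58.1. Values were log2(quantile-normalized intensity + 9), where 9 is the 25th percentile of the deposited values. Fold changes are on that scale and understate the change of dim genes. A probe set was kept if it lay at or above the array's median on at least 3 of 6 arrays, which left 22997, of which 20268 had 1 symbol. The probe set with the highest mean stood for its gene, giving 12442 genes, of which 4937 had several kept probe sets. XY was compared with XX by lmFit and eBayes with Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Y-linked probe sets were tested without the filter, over all 45037. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Single values per array were compared by exact two-sided permutation tests, which with 3 arrays against 3 cannot give a p below 0.1. The number of arrays, 3 per group, limits the precision of each value.

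A total of 27 gene lists and 9 lists of markers of other cells were fixed before the data were examined, as was the rule for named genes. It takes the 12 largest rises and the 12 largest falls among genes past the adjusted p whose XX and XY values do not overlap, the Y-linked genes, the X-linked partners of Y genes, and up to 4 members of each list with the smallest p. X-linked genes and markers named beyond it were chosen after their values were seen, and this is said where they appear.

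The steps were tested on simulated data. With 200 of 12442 genes changed, 2.99% of genes changed 1.5-fold, 34.0% of those changed 2-fold and 78.5% of those changed 4-fold were recovered, and 4.96% of calls were false. A shift of -0.3 put into X-linked genes came back as -0.31, and camera called it in 20 of 20 runs, against 0 of 20 runs with no shift. The simulated noise was drawn independently for each gene and array, without correlation between genes or array effects. These runs therefore do not give the error rates of limma or camera where genes move together. Alternatives covered the scaling, pseudocount, filter, probe sets per gene, variance model, array weights, replicate block, threshold and correlation, and leaving out each array in turn. Added after the data were seen were trimmed mean scaling, the Actb control ratio as a covariate, and XX 1 alone against the XY arrays.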

Results

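The data comprised 6 arrays, 3 of XX and 3 of XY oocytes, each made from 10 fully grown GV oocytes. The comparison addressed which transcripts stored in the fully grown oocyte differ between XY females and their XX littermates. Arrays correlated at 0.967 to 0.983 within XX, at 0.980 to 0.982 within XY and at 0.940 to 0.962 between the groups, over 12442 genes. The first principal component held 55.9% of the variance and separated XX from XY. On it XX 1, at -14.0, lay between XX 2 and XX 3 (-41.3 and -43.2) and the XY arrays (28.3 to 37.2). XX 1 correlated with XX 2 and XX 3 at 0.967 and with XY 1 at 0.962. The second component held 16.7% and set XX 1 apart from the other 5 arrays.

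Of the Y-linked genes, Uba1y, Eif2s3y, Uty and Zfy2 were higher in XY oocytes. Uba1y, a Y-linked ubiquitin-activating enzyme, had a deposited intensity of 3996 ± 562 (SD, n = 3) in XY against 15.4 ± 10.6 (SD, n = 3) in XX. Its log2 change was 7.59 ± 0.32 (SE), with limma's adjusted p = 0.00105. Eif2s3y, the Y-linked gamma subunit of translation initiation factor eIF2, rose by 5.38 ± 0.45 (adjusted p = 0.0180), from 6.28 ± 10.4 to an intensity of 500 ± 162. Uty, a relative of the histone demethylase Kdm6a, rose by 2.04 ± 0.23 and the zinc finger gene Zfy2 by 1.44 ± 0.24. Of 20 Y-linked probe sets of 9 genes, 5 probe sets of 4 genes rose among all 45037 probe sets tested, 8 rose adjusted over the list alone, and 0 fell. The 3 further probe sets were of Kdm5d, with a log2 change of 1.70, Usp9y, with 1.33, and Orly, with 0.83. The count of 5 became 0 with no pseudocount, with XX 1 alone or with the Actb control ratio as a covariate, 1 with the replicate block, 3 without XX 2, 2 without XX 3, and 1 without XY 1, XY 2 or XY 3. Over the alternatives run on genes, the log2 change stayed positive. It ran from 5.83 to 8.37 for Uba1y, 3.82 to 7.69 for Eif2s3y, 1.27 to 2.64 for Uty and 1.05 to 1.72 for Zfy2. Other probe sets of Uty, Kdm5d, Orly and Eif2s3y did not pass, and neither did those of Sry, the testis-determining gene (-0.66 and 0.13), or Tspy-ps (0.54).

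**Figure D1:**
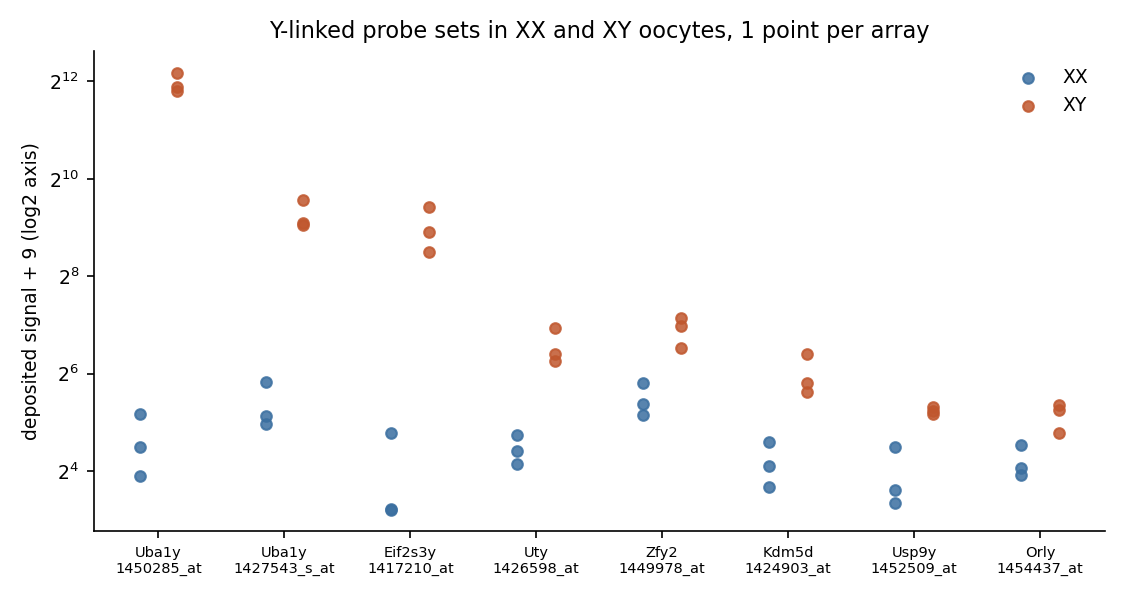
Deposited intensity plus 9, on a log2 axis, of the 8 Y-linked probe sets past the threshold adjusted over the list alone, 1 point per array, XX in blue and XY in orange. The 3 XY points lie above the 3 XX points for each probe set, from Uba1y to Orly, whose log2 changes in quantile-normalized values, not drawn here, were 7.59 and 0.83.

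Among the 12442 genes, 1643 changed past the adjusted p, 978 of them higher and 665 lower in XY oocytes. Of these, 826 differed at least 2-fold, 514 upward and 312 downward, and the median log2 change was 1.02 for genes that rose and -0.96 for genes that fell. The XX and XY values of all 1643 did not overlap, as held for 38.8% of all tested genes against 10% by chance. The potassium channel gene Kcnj13 (chromosome 1) rose by 3.62 ± 0.15 (log2 ± SE, adjusted p = 0.000253), with XX at 6.54 ± 0.05 and XY at 10.16 ± 0.18 (SD, n = 3 each). The corepressor gene Ripply3 (chromosome 16) rose by 3.51 ± 0.35, Mst1 (chromosome 9), which encodes macrophage-stimulating protein, by 3.12 ± 0.31, and the organic anion transporter gene Slco1a4 (chromosome 6) by 3.00 ± 0.19. Further large rises were those of the syntaxin gene Stx19 (2.96), the angiotensin receptor gene Agtr1a (2.93), the ceramidase gene Acer1 (2.85), the fetal plasma protein gene Afp (2.82) and the insulin receptor adaptor gene Grb14 (2.81). X-linked Bex1 rose by 3.05 ± 0.74, with XX values spread by an SD of 1.70.

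The largest fall in the main setting was that of Bhlhe40 (chromosome 6), a circadian transcriptional repressor, at -2.98 ± 0.31 (adjusted p = 0.00443). The adenylate kinase gene Ak5 (chromosome 3) followed at -2.67 ± 0.40, and Chst11 (chromosome 10), a chondroitin sulfotransferase gene, at -2.54 ± 0.22. X-linked Ammecr1 (-2.43), Fam199x (-2.31) and the phosphatidylinositol phosphatase gene Ocrl (-2.14) also fell, although the other kept probe set of Ocrl went the opposite way. Osbpl5 (-2.39), an oxysterol-binding protein gene, Tenm3 (-2.22), a teneurin gene, Fstl1 (-2.13), a follistatin-like gene, Pwwp2a (-2.09), which encodes a chromatin reader, Bcdin3d (-2.08), an RNA methyltransferase gene, and Dennd6a (-2.08) completed the 12 largest falls. In XY, Bhlhe40 (3.96), Ammecr1 (3.78), Bcdin3d (3.74) and Osbpl5 (3.62) lay near the floor that the pseudocount sets. The size and rank of their falls depend on it. Over the alternatives Bhlhe40 ran from -4.17 to -1.82 and Osbpl5 from -4.11 to -1.23. Among the rises, the same held for Acer1, at 3.52 in XX, with changes of 1.52 to 5.04. Of the 24 genes, 22 passed in each alternative that tested them, other than XX 1 alone and the Actb covariate; 6 of the 24 were not tested under the 70th percentile filter. Bex1 did not pass without XX 2 (adjusted p = 0.0651), XX 3 (0.119), XY 1 (0.0999), XY 2 (0.103) or XY 3 (0.0920), and Fstl1 did not without XX 2 (0.0749) or XX 3 (0.0974). With no pseudocount or no filter, Bex1 (0.0936 and 0.0700) and Fstl1 (0.0661 and 0.0534) did not pass either.

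**Figure D2:**
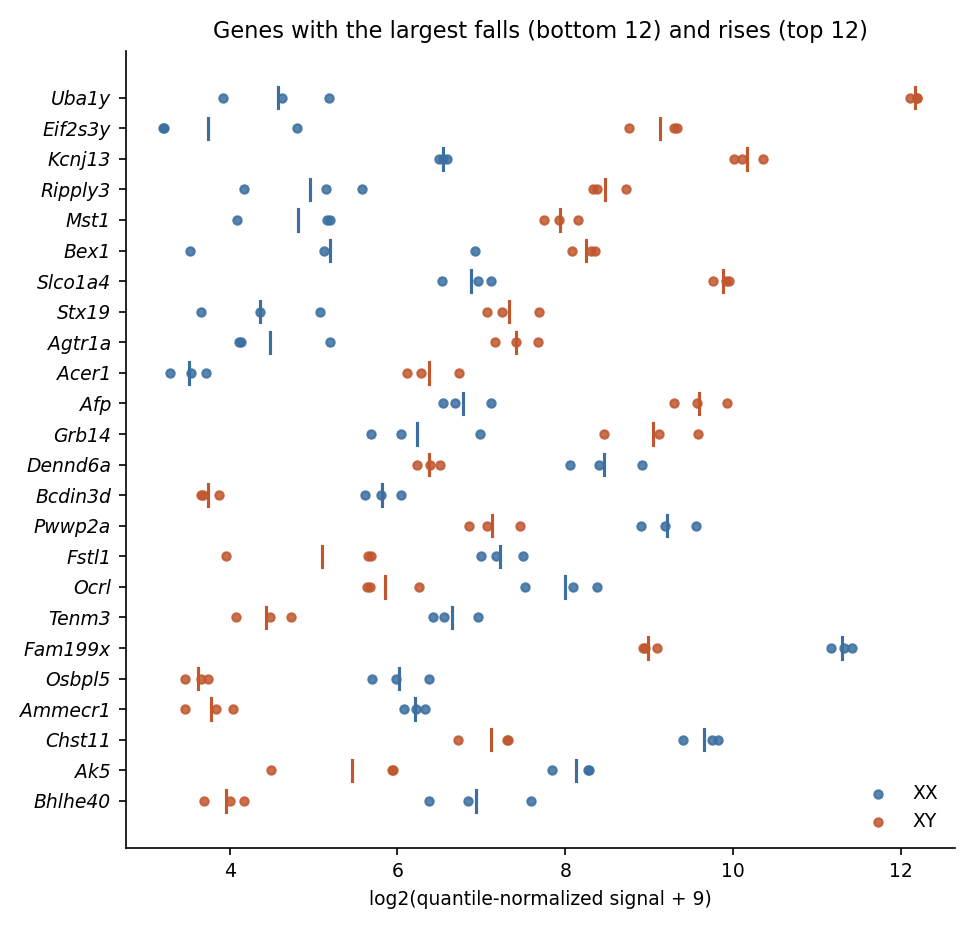
Log2(quantile-normalized intensity + 9) of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom), 1 point per array, with the mean of 3 arrays as a bar, XX in blue and XY in orange. The groups do not overlap for any of the 24 genes, and the log2 changes run from 7.59 for Uba1y to -2.98 for Bhlhe40.

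The arrays within XX were not alike in RNA quality. The 5' control of Actb read 184 and 188 in XX 2 and XX 3, against 45.9 in XX 1 and 55.7, 62.7 and 54.7 in XY 1, XY 2 and XY 3. The 5' control of 18S rRNA read 3236 and 3620 in XX 2 and XX 3, against 626 in XX 1 and 574 to 896 in XY. The log2 ratio of 3' to 5' Actb signal was 4.34 ± 0.82 in XX and 5.36 ± 0.34 in XY (SD, n = 3 each, exact permutation p = 0.2), and that of Gapdh was 3.42 ± 0.52 and 4.03 ± 0.13 (exact permutation p = 0.2). With the Actb ratio as a covariate, which leaves fewer degrees of freedom, 126 genes passed, 88 higher and 38 lower. The count of 1643 became 3248 without XX 1, 625 without XX 2, 598 without XX 3, 584 without XY 1, 487 without XY 2 and 565 without XY 3. It also moved with the scaling: 472 higher and 529 lower with the deposited values, 482 and 1622 with median scaling, and 1423 and 586 with trimmed mean scaling. The median log2 change of all genes was 0.07 in the main setting and -0.12, -0.27 and 0.18 under these scalings. Directions were counted against 0 and not against this median, so the numbers of higher and lower genes carry it.

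X-linked genes were lower in XY oocytes as a group. Of 375 tested, 95 fell (25.3%) and 16 rose (4.27%), against 564 (4.70%) and 956 (7.96%) of 12004 autosomal genes. The X-linked median, relative to that of autosomal genes on the same array, was -0.37, -0.32 and -0.27 in XX 1, XX 2 and XX 3 and -0.63, -0.53 and -0.66 in XY 1, XY 2 and XY 3. The difference of -0.29 ± 0.05 (SE) had an exact permutation p of 0.1, the smallest that 3 against 3 can give. As a set, X-linked genes were lower than autosomal ones by camera (p = 1.62e-09, and p = 0.00501 with an estimated correlation). The X-linked minus the autosomal median of log2 changes was -0.355 over all tested genes, and its size grew with expression. It was -0.08 among the 147 X-linked genes of the dimmest of 3 equal groups by mean level and -0.51 among 123 in the middle. Among 105 in the brightest it was -0.80, and there 55 fell and 0 rose. The difference of per-array medians, -0.29 in the main setting, was -0.08 with no filter on low values and -0.63 with a 70th percentile filter.

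Genes on the X with a relative on the Y made up 8 of the 375, and 5 of them fell. Kdm6a, a histone H3 demethylase gene, fell by 1.56 ± 0.24 (SE, adjusted p = 0.0110), the demethylase gene Kdm5c fell by 1.45 ± 0.32 and the deubiquitinase gene Usp9x fell by 1.36 ± 0.22. The zinc finger gene Zfx fell by 1.32 ± 0.16, but not as the mean of its probe sets (adjusted p = 0.0837), and the RNA helicase gene Ddx3x fell by 0.98 ± 0.19. Eif2s3x (-1.01, adjusted p = 0.0688), Sox3 (0.17) and Rbmx (-0.09) did not pass, and another probe set of Rbmx went the opposite way. Adjusted over the list alone, 6 fell. The list passed camera (adjusted p = 0.000703), but not with an estimated correlation (adjusted p = 0.323). All 8 members are X-linked, and camera compares them with all other genes, most of them autosomal. The call is therefore not separate from the fall of X-linked genes as a group, of which 55 of 105 in the brightest group fell. Whether the partners fell more than other X-linked genes was not tested. Without XX 3, Usp9x (adjusted p = 0.0531), Ddx3x (0.0610) and Kdm5c (0.0757) did not pass. Ddx3x also missed without XX 2 (0.0683), XY 1 (0.0622), XY 2 (0.0733) or XY 3 (0.0613), and Kdm5c without XX 2 (0.0909), XY 1 (0.0849) or XY 3 (0.0868) or with no filter (0.0558).

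Among the RNAs and regulators of X inactivation, Rlim, a ubiquitin ligase gene, fell by 0.95 ± 0.19, Xist, the RNA that coats the inactive X, rose by 0.81 ± 0.21 from a low level (5.65 in XX and 6.46 in XY), and Jpx had a log2 change of -0.04. Rlim did not pass without XX 2 (adjusted p = 0.0741), XX 3 (0.0648), XY 1 (0.0710), XY 2 (0.0707) or XY 3 (0.0749). The call for Xist was lost without XX 2 (adjusted p = 0.131), XX 3 (0.124), XY 1 (0.0694), XY 2 (0.140) or XY 3 (0.118), and with the deposited values (0.0700) or median scaling (0.0667), no pseudocount (0.0537), no filter (0.0858) and a trended variance (0.0522).

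**Figure D3:**
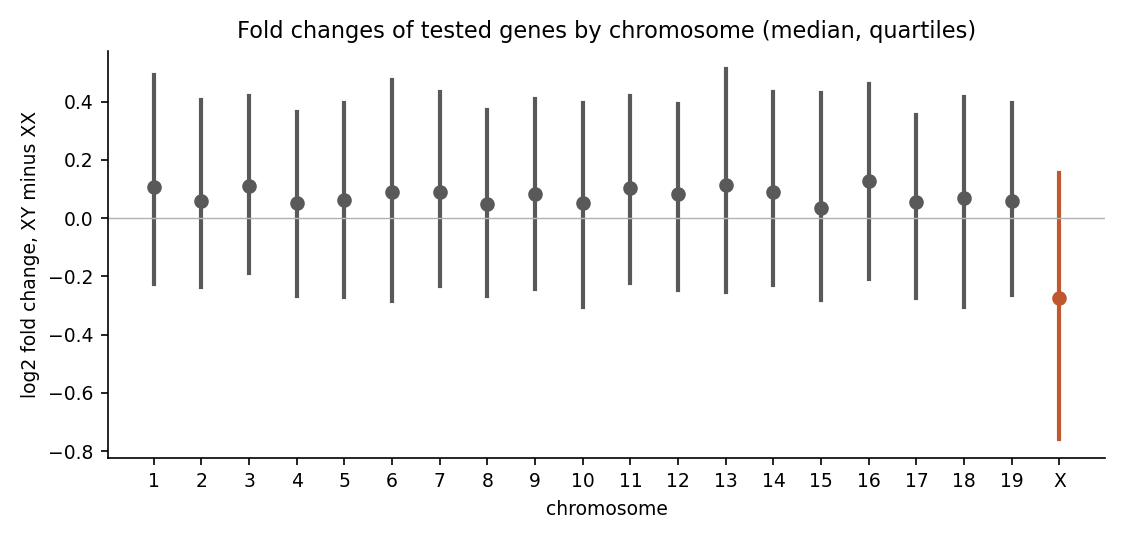
Log2 change from XX to XY of tested genes by chromosome, with the median as a point and the quartiles as a line. The X chromosome lies at -0.28, while the medians of the 19 autosomes lie between 0.04 and 0.13.

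The Y-linked list passed camera with no filter (adjusted p = 2.06e-05). After the filter, which 4 of its 5 measured genes passed through their XY arrays alone, the adjusted p was 2.02e-05, and 0.195 with an estimated correlation, and its direction was then largely set by the filter. Of the 27 lists, 4 passed, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05 by camera. Beyond the Y-linked list and the X-linked partners, the 4 included oocyte-specific growth and identity genes, which were lower, and oxidative phosphorylation genes, which were higher. By limma's fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 8 lists passed: the Y-linked genes (adjusted p = 0.000434), their X-linked partners (0.0152), oocyte-specific genes (0.0362), maternal mRNA storage and decay (0.0362), glycolysis (0.0181), the tricarboxylic acid cycle (0.0176), antioxidant defence (0.0362) and histones (0.0397). Oxidative phosphorylation did not (0.0537).

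Of 22 measured oocyte-specific genes, 0 rose and 2 fell, with a median log2 change of -0.14, or -0.49 with the deposited values and -0.66 with median scaling, where all genes had medians of 0.07, -0.12 and -0.27. The counts were the same adjusted over the list alone. Bmp15, an X-linked gene for an oocyte-secreted growth factor, fell by 1.34 ± 0.20, and Gja4, the connexin 37 gene of the gap junctions between oocyte and granulosa cells, fell by 1.03 ± 0.20. The linker histone gene H1f8 (-0.74, adjusted p = 0.0535) and Oosp2 (-0.48, adjusted p = 0.0618) did not pass. The list had an adjusted p of 0.00663, which was 0.724 with an estimated correlation, 0.0198 without its X-linked member and 0.0616 with the Actb covariate. Gja4 did not pass without XX 2 (adjusted p = 0.0732), XX 3 (0.0627), XY 1 (0.0673), XY 2 (0.0739) or XY 3 (0.0647).

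Of 61 measured oxidative phosphorylation genes, 8 rose and 0 fell, and adjusted over the list alone 15 rose and 2 fell. Atp5g3, a subunit of the mitochondrial ATP synthase, rose from a mean log2 level of 10.4 in XX to 11.4 in XY (SE of the change 0.16), Ndufs8 rose by 0.89 ± 0.18 and Ndufs1 by 0.78 ± 0.15, both of complex I, and cytochrome c1, Cyc1, by 0.83 ± 0.14. With the deposited values none of these passed, with Atp5g3 at 0.63 (adjusted p = 0.193), Ndufs8 at 0.53 (0.26), Ndufs1 at 0.47 (0.381) and Cyc1 at 0.47 (0.342), nor with median scaling (adjusted p from 0.202 to 0.44). Ndufs8 also missed with no filter (0.0511) and as the mean of its probe sets (0.0761). The median log2 change was 0.29, and it was -0.02 with the deposited values and -0.18 with median scaling, where all genes had medians of -0.12 and -0.27. The adjusted p was 0.0167, or 0.800 with an estimated correlation. Setting aside XX 1 alone, a lone sample, the list did not pass under the deposited values (adjusted p = 0.649), median scaling (0.814), trimmed mean scaling (0.269), the Actb covariate (0.382) or without XX 2 (0.0857). With each gene's log2 level centred over the arrays, the list's median relative to all genes was 0.02, -0.19 and -0.19 in XX 1, XX 2 and XX 3. It was 0.09, 0.11 and 0.09 in XY 1, XY 2 and XY 3. This measure compares arrays and does not give how highly the genes were expressed.

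Other energy and redox lists did not pass camera, and single members passed limma's test. The antioxidant genes Gpx1 and Gpx4, both glutathione peroxidases, rose by 2.76 ± 0.32 and 1.17 ± 0.17, and the quinone reductase gene Nqo1 by 1.16 ± 0.15, among 19 measured with 3 higher and 0 lower (list adjusted p = 0.495). Glycolysis and pyruvate genes had 3 of 23 higher and 0 lower (adjusted p = 0.302), among them the aldolase gene Aldoc (1.16) and the pyruvate dehydrogenase genes Dlat (0.60) and Pdhb (0.65). In the tricarboxylic acid cycle, 1 of 18 genes rose, Suclg2 at 0.78 (adjusted p = 0.558 for the list). With the deposited values Gpx4 (0.80, adjusted p = 0.143), Dlat (0.25, 0.616), Pdhb (0.28, 0.563) and Suclg2 (0.42, 0.474) did not pass, nor with median scaling (adjusted p from 0.14 to 0.813). The calls of these 4 genes also ended in at least 1 of the settings with no filter, no pseudocount, trimmed mean scaling or the mean of probe sets (adjusted p from 0.0503 to 0.14).

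Genes for storing and degrading maternal mRNA had 1 of 26 higher and 3 lower, with a median of -0.21 (-0.54 with the deposited values and -0.70 with median scaling) and an adjusted p of 0.0511 (0.518 with an estimated correlation). The list passed in 12 of 19 alternatives, among them the deposited values (adjusted p = 0.00794), with a range of 0.00725 to 0.388. Pabpn1l, an oocyte poly(A)-binding protein gene, fell by 1.61 ± 0.21, the deadenylation gene Pan3 by 1.76 ± 0.43 and Cpeb1, which controls cytoplasmic polyadenylation, by 0.86 ± 0.21, while the uridylyltransferase gene Tut4 rose by 0.54 ± 0.14. Of 25 maternal effect genes, 2 rose and 3 fell (list adjusted p = 0.220). Khdc3, a component of the subcortical maternal complex, rose by 1.85 ± 0.23 and Basp1 by 1.11 ± 0.22, whereas X-linked Ube2a fell by 1.43 ± 0.16. Ago2 fell by 1.03 ± 0.26, and had a value of 0.22 as the mean of its probe sets. Among ubiquitin ligases and deubiquitinases, 0 of 28 rose and 5 fell (list adjusted p = 0.0950, past the threshold in 6 of 19 alternatives, from 0.00869 to 0.666, and 0.800 with an estimated correlation), including X-linked Ube2a, Usp9x and Cul4b (-0.94). With the deposited values Tut4 (0.64, adjusted p = 0.154) and Basp1 (0.83, 0.0675) did not pass, nor with median scaling (0.144 and 0.0642). The calls of Pan3, Cpeb1, Tut4 and Ago2 also ended in at least 1 of the other settings of pseudocount, filter, scaling or variance model (adjusted p from 0.0517 to 0.167).

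**Figure D4:**
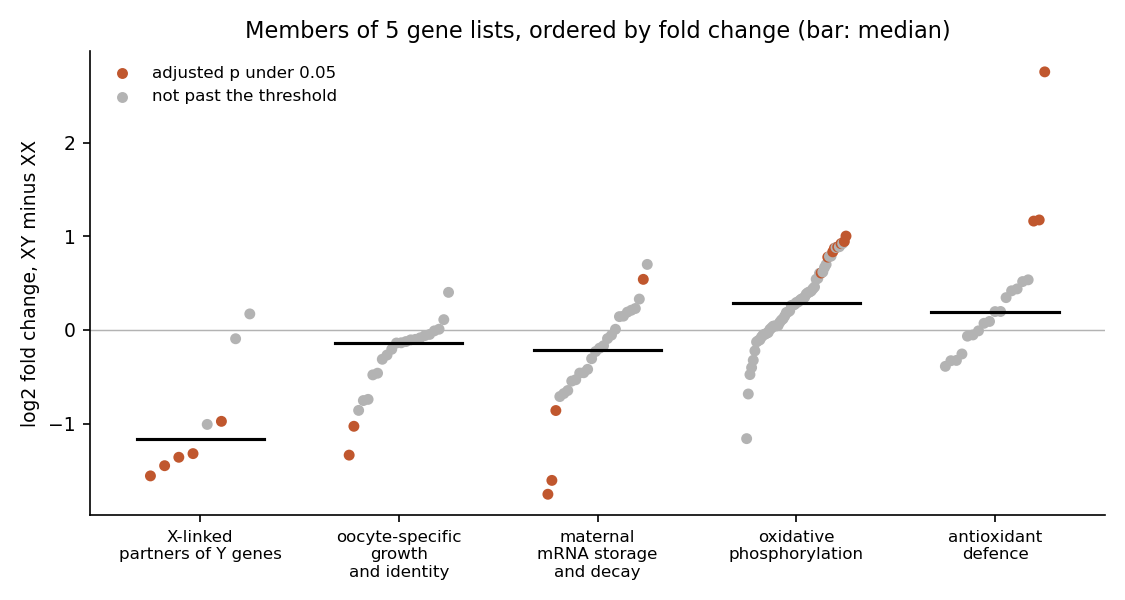
Log2 change from XX to XY of the measured members of 5 gene lists, 1 point per gene, orange where the adjusted p was under 0.05 and grey otherwise, with the list's median as a bar. Medians were -1.16 for X-linked partners of Y genes, -0.14 for oocyte-specific genes, -0.21 for maternal mRNA storage and decay, 0.29 for oxidative phosphorylation and 0.20 for antioxidant defence. With the deposited values and with median scaling they were -1.29 and -1.45, -0.49 and -0.66, -0.54 and -0.70, -0.02 and -0.18, and -0.14 and -0.30, in the same order.

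None of the lists of genes of meiosis and the germ line passed camera. Of 27 genes of meiotic arrest and resumption, 1 rose and 3 fell (list adjusted p = 0.779): the anaphase inhibitor gene Fbxo5 (also called Emi1) fell by 0.83, the kinase gene Mos by 0.85 and the phosphodiesterase gene Pde3a by 0.68, while Cdk1 rose by 0.60. Cohesin and condensin genes had 1 of 25 higher, Ncapg2 at 0.75, and 2 lower, Stag1 at -1.36 and Esco2 at -1.34 (adjusted p = 0.558). Spindle and checkpoint genes had 1 of 30 higher, Tpx2 at 0.65 (adjusted p = 0.982), and meiotic recombination genes had 0 of 16 past the threshold (limma, 4 at an unadjusted p under 0.05; list adjusted p = 0.982; Rec114, with the smallest p, had 0.54). Of 24 DNA damage response genes, Fancd2 (0.86) and Rad50 (0.64) rose (list adjusted p = 0.558). Among 22 transposon silencing genes, 3 rose and 3 fell (adjusted p = 0.899), with Piwil2 (1.05), Mael (0.82) and Ddx4 (1.01) higher and Piwil1 (-0.97) lower. Of 15 transcripts of the male germ line, 2 rose, Ldhc at 2.35 and Hspa2 at 0.86, and 3 fell, among them Brdt at -0.81 (adjusted p = 0.522). With the deposited values Pde3a (-0.68, adjusted p = 0.132), Cdk1 (0.23, 0.69), Ncapg2 (0.40, 0.494), Tpx2 (0.28, 0.601), Fancd2 (0.55, 0.276), Rad50 (0.29, 0.579), Mael (0.45, 0.426), Ddx4 (0.68, 0.149) and Hspa2 (0.81, 0.0859) did not pass, and all but Pde3a missed with median scaling too (adjusted p from 0.0786 to 0.885). The calls of Mos, Pde3a, Cdk1, Ncapg2, Esco2, Tpx2, Rad50, Mael, Ddx4, Brdt and Fancd2 also ended in at least 1 other setting of pseudocount, filter, scaling, probe sets or variance model (adjusted p from 0.0503 to 0.149).

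Lists of chromatin genes did not pass camera either. Dnmt3b rose by 1.43 ± 0.15 and Mbd1 by 0.71, while the de novo DNA methyltransferase gene Dnmt3a fell by 0.62 and the imprinted gene Mest by 0.88, among 19 genes of DNA methylation and imprinting (adjusted p = 0.495). Of 33 histone-modifying enzymes, Kdm5b rose by 1.91 ± 0.18 and Hdac1 by 0.83, and Suz12 (-0.73) and Setd1b (-0.97) fell (adjusted p = 0.346). Among 14 genes of histones and histone mRNA processing, Asf1b rose by 0.63 (adjusted p = 0.899). Of 27 chaperone and unfolded protein genes, 1 rose, Hspd1 at 0.73, and 4 fell, among them Hsp90b1 at -1.42 and Pdia3 at -1.31 (adjusted p = 0.522). Of 22 apoptosis genes, X-linked Xiap fell by 1.57 and Diablo rose by 0.79 (adjusted p = 0.899). Of 33 proteasome genes, Psmc6 (0.64) rose and X-linked Psmd10 (-0.80) fell (adjusted p = 0.899). Of 30 translation factor genes, Eif4ebp1 (1.08) and Pabpc1 (1.24) rose and X-linked Eif1ax (-0.96) fell (adjusted p = 0.854). Of 34 RNA polymerase II and splicing genes, 3 rose, among them Snrpb (1.68) and Polr2h (1.29), and 2 fell, among them Hnrnpa2b1 (-0.89) (adjusted p = 0.899). None of 42 cytosolic ribosomal protein genes passed (limma, 8 at an unadjusted p under 0.05; list adjusted p = 0.522; Rpl7, with the smallest p, had 0.80), and the list of X inactivation RNAs did not either (adjusted p = 0.899). With the deposited values Mbd1 (0.38, adjusted p = 0.457), Dnmt3a (-0.98, 0.0584), Hdac1 (0.62, 0.19), Asf1b (0.25, 0.626), Hspd1 (0.37, 0.439), Diablo (0.49, 0.298), Psmc6 (0.27, 0.604) and Pabpc1 (0.89, 0.0672) did not pass, and all but Dnmt3a missed with median scaling too (adjusted p from 0.0742 to 0.821). The calls of Mbd1, Dnmt3a, Mest, Setd1b, Asf1b, Hspd1, Pdia3, Psmc6, Psmd10, Pabpc1 and Eif4ebp1 also ended in at least 1 other setting of pseudocount, filter, scaling or probe sets (adjusted p from 0.0513 to 0.299).

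Of 110 named genes past the adjusted p, 45 passed without each array in turn, with 1 call lost without XX 1, 52 without XX 2, 55 without XX 3, 53 without XY 1, 59 without XY 2 and 53 without XY 3. Median and mean had opposite signs for male germ line transcripts (-0.29 and 0.03), chaperones (0.10 and -0.06) and meiotic arrest and resumption (0.02 and -0.09), and camera's direction was down, against a positive median, for the last 2 and for the spindle, recombination, Sertoli and endothelial lists.

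Markers of other cells were compared in the same way, and 0 of the 7 lists with enough measured genes passed camera with Benjamini-Hochberg adjustment (1 with an unadjusted p under 0.05, leukocytes). The median level of 11 cumulus and granulosa markers was 6.09, 5.79 and 5.54 in XX 1, XX 2 and XX 3 and 6.84, 6.81 and 6.52 in XY 1, XY 2 and XY 3 (exact permutation p = 0.1). Of these markers, Inha, chosen like the next ones after the values were seen, rose by 1.58 ± 0.41, but not without XX 2 (adjusted p = 0.141), XX 3 (0.132), XY 1 (0.124), XY 2 (0.121) or XY 3 (0.0920). Gja1 had 2.59 ± 0.75 (adjusted p = 0.0619) and Kitl -0.63 (adjusted p = 0.0715). The leukocyte markers Csf1r and Cd68 rose by 1.40 and 0.59 (list adjusted p = 0.160), and the smooth muscle marker Myh11 fell by 0.93 (0.257); by fry both lists had an adjusted p of 0.0330. Cd68 did not pass with the deposited values, median scaling (0.131), no filter (0.0821), 4 times the pseudocount (0.0698) or a trended variance (0.118), and Inha did not with no filter (0.0836) or no pseudocount (0.0672). Cumulus and granulosa (0.477), theca (0.437), stromal (0.543), Sertoli (0.798) and endothelial (0.950) lists had a camera adjusted p above the threshold. Erythroid and ovarian surface epithelium markers had too few measured genes for the test.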

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

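The tests of the X-linked shift against RNA quality and against other chromosomes, of oxidative phosphorylation against brightness and of the cumulus markers were chosen after the results were seen, as was trimmed mean scaling as 1 of the 3 scalings used for the 1643 genes, and the other tests before.

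Probe sets with no gene symbol listed were outside the comparisons of named genes, and 75 of the 2147 kept ones were higher in XY than in XX oocytes and 89 lower, with log2 changes of up to 6.09. Their genes are not named here.

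The 1643 genes that differed between XX and XY oocytes coincided with brightness, control ratios and cumulus markers that also differed between arrays. Unequal brightness was tested with 3 other scalings, under which the lowest share of these genes that kept call and direction was 52.9%. This lay just above the limit of 50% set for it. Quantile normalization had already removed any factor shared by all genes of an array. The share kept is therefore no test of such a factor, and shows only how far the calls depend on the scaling. The 52.9% came from the deposited values, which keep the unequal brightness, and the median and trimmed mean scalings apply a single factor per array. Brightness that acts differently on dim and bright genes therefore stays open. RNA quality of XX 2 and XX 3 stays open. Genes called without XX 1 and XY 1 kept 0.407 of their change between these 2 arrays (median of those that rose, 0.44 of those that fell). This lay between the limits of 0.25 and 0.5 set for it. The quotients were 0.508 and 0.532 with XX 1 and XY 2 left out, and 0.516 and 0.492 with XX 1 and XY 3. These runs without XX 1 called 1862 to 2174 genes, while runs that kept XX 1 and left out XX 2 or XX 3 called 1 to 3. Genotype cannot be told apart from RNA quality for part of the genes. No processing batch is known from the labels, so 1 shared by XX 1 and the XY arrays was not tested and stays open too. Adhering cumulus cells also stay open for genes that rose. The 11 measured markers, 0 of them in another list, had a median log2 change of 0.40, between the limits of 0 and 1 set for it. Of these, 8 were positive (Gja1 2.59, Inha 1.58 and Fshr 0.89 the largest) and 3 negative (Kitl -0.63, Nr5a2 -0.16 and Inhbb -0.07). The median level of the 11 markers was 0.916 higher in XY, with each XY array above each XX array, although the oocytes had been stripped of these cells. Only 1 of the 11, Nr5a2 at 9.75, lay above the median XX level of tested genes, 7.89, and it did not rise. The higher median level thus rests on dim markers. The real grouping gave 1643 genes and the highest of the other 9 splits 0 by limma, and 10 splits are too few for a share under 0.05. Each of the other splits mixed XX and XY arrays in both groups, so any XX to XY difference widened their spread within groups. A count of 0 there was therefore largely set by the design.

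The X-linked shift of -0.29 was also weighed against technical causes. RNA quality as its whole cause is argued against by the fit with the Actb ratio as a covariate. That fit left a shift of -0.22 ± 0.06 (SE), more than 2 standard errors below 0. Dim probe sets as its whole cause are argued against by the brightest genes, at -0.80 in X-linked minus autosomal median log2 change. By median log2 change, the largest shift of an autosome against the others was 0.0523, against 0.355 for the X. For 1 X chromosome in place of 2, the limit set beforehand was a fall in the brightest genes smaller than the -0.80 seen. Any decrease across the X at least as large as that limit would meet it, whatever its cause. The value of -0.80 thus restates the shift and is not a separate test of X dosage. That hypothesis remains a candidate explanation. Without XO oocytes, 1 X and the presence of a Y are not separated. The real grouping gave 0.287 and the highest other split 0.177, with too few splits for a share under 0.05. The other splits mixed XX and XY arrays in both groups, which shrinks such a shift.

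Oxidative phosphorylation genes were higher in XY in the main setting, but not past the threshold with an estimated correlation (0.152 between genes, adjusted p = 0.800), which random lists do not carry, so that these weigh level and brightness alone and a chance shift shared by these genes stays open. Their level of expression is argued against as the cause, since the list's median lay at the 99.99 percentile of 10000 level-matched random lists. Unequal brightness that acts alike on genes of 1 level is argued against too, since the deposited values, which keep it, put the list at percentile 100 of such lists (median -0.02 against -0.28); the other scalings gave 99.99 to 100, but a factor per array moves such lists alike, so they add little, and camera against all genes passed under none of the 3 (lowest adjusted p = 0.269). RNA quality stays open: XX 1 lay 0.0647 below the lowest XY array, more than their range of 0.0229, but XX 1 is a single array, it lay nearer to the XY arrays than to XX 2 and XX 3, and with the Actb covariate, which leaves fewer degrees of freedom, the list's median went from 0.29 to 0.11 and the list did not pass (adjusted p = 0.382, within 0.00185 to 0.814 over the alternatives).

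Without its X-linked member, the oocyte-specific list had a camera p of 0.00238, so that this gene alone did not make the call. The whole list did not pass with an estimated correlation (adjusted p = 0.724) or with the Actb covariate (0.0616). Cumulus cells stay open for it too. Their markers had a median level 0.916 higher in XY but a median log2 change of 0.40, and as a list did not pass camera (adjusted p = 0.477). Without its 4 X-linked members, the ubiquitin ligase list had a camera p of 0.315, and the whole list did not pass with an estimated correlation (adjusted p = 0.800). For Y-linked probe sets the real grouping gave 5 and the highest other split 0, and for gene lists 4 and 1. In each case 1 of the 10 splits, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. Here too the other splits mixed XX and XY arrays in both groups, which lowers their counts.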

How the results depend on the processing

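Trimmed mean scaling, the Actb covariate and XX 1 alone were chosen after the data were seen. The X-linked shift kept its direction and its camera call in every alternative run, from -0.08 to -0.63, and the differences in the Actb and Gapdh control ratios moved by less than the spread between arrays with either other pseudocount. Of 2334 alternative values of 124 named genes, 1622 kept direction and side of the threshold, 651 kept direction and lost the call, 43 gained a call and 18 reversed. Without XX 1 alone and the Actb covariate there were 2086 values. Of these, 1571 kept direction and side, 455 lost the call, 43 gained a call and 17 reversed. Over all alternatives, the figures for the 24 genes with the largest changes were 406 of 450, with 44 calls lost and 0 reversed. The reversals were Rbmx (0.24 with trimmed mean scaling, 0.26 as the mean of probe sets, 0.0082 with array weights, and -0.47 to 0.21 without 1 array), Jpx (0.0941 with the deposited values, 0.32 with trimmed mean scaling, 0.12 with array weights, and -0.20 to 0.22 without 1 array), Inhbb (0.0519 with the deposited values, 0.27 with trimmed mean scaling, 0.0164 with 4 times the pseudocount, 0.0293 with array weights, and -0.44 to 0.57 without 1 array), Ago2 (0.22 as the mean of probe sets) and Sox3 (-0.0458 with XX 1 alone). Rbmx, Jpx, Inhbb and Sox3 were not called in the main setting.

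The count of 1643 genes became 1001 with the deposited values, 913 with no filter, which tests more genes, and 3264 with array weights. It was 126 with the Actb covariate, which leaves fewer degrees of freedom, and 1 with XX 1 alone, a lone sample assumed to vary like the XY arrays, which says nothing about stability, 1043 at an unadjusted p under 0.05 with at least 2-fold, and 3019 at an adjusted p under 0.10. Leaving out 1 array gave 487 to 3248. The Y-linked count of 5 probe sets became 0 with no pseudocount, with the Actb covariate and with XX 1 alone, and 1 to 5 without 1 array. The 4 gene lists became 7 with median scaling, 2 with the Actb covariate and 0 with an estimated correlation, and 3 to 6 without 1 array. Under median scaling these included maternal mRNA storage (adjusted p = 0.00725), ubiquitin ligases (0.00953), maternal effect genes (0.0359) and histone-modifying enzymes (0.0476). Where no construction is named, the cause was not tested.

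Replicate numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated at -0.10, 0.00 and -0.04, and in these deviations no XX array correlated best with the XY array of its own number. In log2 levels XX 1, XX 2 and XX 3 each correlated best with XY 1 (0.962, 0.951 and 0.950). With the replicate block, which leaves fewer degrees of freedom, 679 genes and 1 Y-linked probe set passed. Signal over background limits dim genes, which quantile normalization and the pseudocount of 9 pull together.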

Other observations

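All values in this part were looked at after the results were seen, and no cause was tested for them.

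Among the 16 X-linked genes that rose, beside Bex1, were Bex3 of the same family, at 1.97 ± 0.37 (SE, adjusted p = 0.0191), Tceal8, at 1.93 ± 0.39, and Bhlhb9, at 2.04 ± 0.45. Without XX 3, Bex3 (adjusted p = 0.0731), Tceal8 (0.0644) and Bhlhb9 (0.0764) did not pass, and the same held without XY 1 (0.0638, 0.0646 and 0.0725) or XY 2 (0.0625, 0.0629 and 0.0854). Bex3 (0.0596) and Tceal8 (0.0668) also missed without XX 2, and Bhlhb9 without XY 3 (0.0793), with no pseudocount (0.0598) and with no filter (0.0556). The glycine receptor gene Glra2 rose by 2.05 ± 0.28, the nucleosome-binding protein gene Hmgn5 by 1.56 ± 0.16 and the protocadherin gene Pcdh19 by 1.54 ± 0.15. Among X-linked genes that fell were Scml2, a Polycomb group gene (-1.90), Yipf6 (-1.88) and the translation termination gene Gspt2 (-1.57). These last 6 genes passed without each array in turn.

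Gene families were also grouped by the stem of their symbols, 71 with at least 15 tested genes, and none passed camera after adjustment. The lowest adjusted p was that of Zbtb genes, transcription factors with a BTB domain, at 0.0584 (adjusted p = 0.953 with an estimated correlation), with 0 of 35 higher, 7 lower and a median log2 change of -0.32. Zfp genes followed at an adjusted p of 0.149, with 13 of 254 higher and 31 lower.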
